A study of Mus musculus with 4 samples.

How the data were processed

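Total RNA of whole hearts was sequenced in 2 libraries from wild-type and 2 from Klf9 knockout mice, per the labels, with male sex given for all 4 samples and an age of 8 weeks for the mice. The labels name no batch, date or litter. Groups and replicate numbers were taken from the sample titles. The aligner, the quantification tool, the genome build and the sequencing depth were not given in the sources used here.

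The authors deposited a single table of 17485 genes, identified by Entrez number and symbol, which holds only comparisons. Per the file headers, it gives a log2 ratio for each of the 4 pairs of a wild-type and a knockout library, with a p-value and a false discovery rate under a name that points to a Poisson model. It also gives a log2 ratio for the groups with a p-value and a q-value from DEGseq, per the file headers. The authors' false discovery rate column reaches 1.0014, above the range of a rate, and was not used beyond counting. The direction of the log2 ratios was read from the column names as knockout over wild type. A Poisson model takes counting as the only error, and how replicates entered DEGseq was not given in the sources used here, so the authors' deposited values were reported only beside a test that uses the spread between replicates.

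The expression value of each library was recovered from the deposited pairwise log2 ratios. In the 16152 genes with all 4 ratios, these were additive to within 9.9e-14, so that they come from 4 numbers per gene. The ratios were resolved by continued fractions into the smallest 4 whole numbers that give them, which were read as values with 2 decimals (step 0.01), where 0 had been replaced by 1 step. Missing ratios (1333 genes) were read as a pair of values at the smallest step. All 17485 genes were resolved, with a largest whole number of 1427365. As a control, 2000 genes were drawn: 100% had whole numbers below 10000000 with the ratios as deposited, and 0% after the ratios were moved by about 1e-06. On 3000 simulated genes 92.4% were recovered exactly and 100% up to a common factor; a factor shared by all 4 values of a gene is lost and makes that gene's level, but not its ratios before the pseudocount, too low. This was expected for 7.61% of genes. Whether the values are FPKM, TPM or another length-scaled unit is not given in the sources used here, and the step of 0.01 is an assumption, so levels are on a scale that is known only up to that step. Of the smallest value, 0.01, it cannot be said whether it was 0.

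The plan written before the data were examined was a count test, with a fallback for tables without counts. No counts were there, so the fallback was the main test: limma 3.58.1 in R 4.3.3 (empirical Bayes with trend and robust settings) on log2(value + 1) of genes with a value of at least 1 in at least 2 libraries, which left 12135 genes, with group as the only term and Benjamini-Hochberg adjusted p below 0.05. No further scaling was applied. A fold change on this scale understates the change of genes with low values. The test was tried on simulated values of the genes already kept by the filter. With 200 of 12135 genes changed, 92% of those changed 2-fold and 100% of those changed 4-fold were recovered. There were 28 false calls among unchanged genes, a larger share of the calls than the 0.05 that the threshold allows. Noise was drawn independently for each gene, and far fewer genes changed than were called in the data. The share of false calls in the data is therefore not known. Values were processed with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.

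Before the data were examined, 41 lists of genes were fixed from textbook knowledge: pathways of mitochondria, metabolism, stress, growth, contraction and inflammation, and markers of other cell types that a heart sample can hold. Lists with at least 5 tested members (34) were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over these lists. Camera compares a list with all other genes. It was repeated with the correlation estimated from the residuals, which rests on 4 libraries, and with fry. With an estimated correlation camera also takes its degrees of freedom from these residuals, so a list can fail for want of libraries alone.

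Genes were named by a rule fixed before the data were examined. It took Klf9, then the 10 largest increases and the 10 largest decreases among genes past the threshold with a mean of at least 1, with both libraries of a group above both of the other and with a symbol that is not a predicted gene. It also took up to 4 members of each pathway list, the 2 with the lowest p in each direction, the 2 members with the highest mean of each cell type list, and Mfn2, Ppargc1a and Tfam. Some genes that the rule takes are not reported here.

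Alternatives chosen before the data were examined were RLE and upper quartile scaling, no filter, a pseudocount of 0.1, non-robust variance moderation, a minimum fold of 1.5, an adjusted p below 0.1, the replicate number as a block, each library left out in turn, and for lists the estimated correlation and fry. Alternatives chosen after seeing the data were a filter of at least 5 in 2 libraries, no mean-variance trend, leaving out genes of the X and Y chromosomes, the member counts of each list without each library, the lists of the closing section without genes already seen and a correction for transcript length and GC content. For that correction, identifiers were matched to a RefSeq gene table of assembly GRCm38.p6, with 17362 of 17485 found there; no coordinates are given because the build used by the authors was not named. Further lists named in the closing section were written after the first results were seen.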

Results

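Bulk RNA sequencing of total RNA from whole mouse hearts compared wild-type animals with animals lacking Klf9, a zinc finger transcription factor of the Krüppel-like family. The labels gave 2 wild-type and 2 Klf9 knockout libraries, male animals and an age of 8 weeks for all 4. The stated purpose was to examine how Klf9 bears on mitochondrial function in the heart, so the single comparison of the design was knockout against wild type. The deposited table held ratios between libraries and not levels or counts, so that the depth of each library is unknown. Expression values per library were recovered from those ratios for 17485 genes, in a unit that was not given, and summed to 426032 and 489534 in the wild-type libraries and to 409359 and 418974 in the knockout libraries. The labels did not say that the libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical in wild type; the knockout libraries differed in Y-linked genes (Kdm5d at 4.01 in replicate 1 and 0.01 in replicate 2).

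Klf9 itself (Entrez 16601) was read first. Its value was 74.9 and 58.8 in the wild-type libraries and 2.66 and 1.99 in the knockout libraries, a log2 fold change of -4.35 ± 0.20 (SE, n = 2 per group; limma, adjusted p = 3.46e-06). Both knockout libraries therefore carried the label's direction. The deleted part of the gene was not given in the sources used here, and sequence outside it can leave a remainder.

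Knockout hearts differed from wild-type hearts across a large share of the transcriptome. The design cannot separate the loss of Klf9 from other differences between the groups, and the closing section raises stage, sex and a transgene. Of 12135 genes tested, 3367 were higher and 2061 lower in the knockout (limma on log2(value + 1), Benjamini-Hochberg adjusted p below 0.05), and 251 of the higher and 177 of the lower genes changed at least 4-fold on that scale. Across genes, Spearman's rho was 0.972 between the wild-type libraries and 0.991 between the knockout libraries, against 0.829 to 0.885 for pairs from different groups. In 75.4% of tested genes both libraries of a group lay above both of the other, where chance gives 33.3%. The median log2 fold change of all tested genes was 0.12, and RLE scaling of the libraries moved it to -0.01 and the split to 2634 higher and 2597 lower, so that the share of higher calls went from 62.0% to 50.4%. Medians of gene lists are therefore given relative to the median of all tested genes, and single genes as fitted. Without knockout replicate 2 the counts were 1859 higher and 1100 lower, and without knockout replicate 1 they were 2195 and 1247; without wild-type replicate 1 there were 3261 lower genes.

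In the authors' deposited table, the DEGseq comparison of the groups had 2321 genes higher and 1426 lower in the knockout at q below 0.001 and an absolute log2 ratio of at least 1. Of the 3024 such genes in the authors' deposited table that were also tested with limma, 2990 passed in the same direction, 34 did not pass and 0 passed in the other direction. Conversely, 4416 of the 9840 tested genes with q below 0.05 in the authors' deposited table did not pass when the spread between replicates was the error. For Klf9 the authors' deposited table gave a log2 ratio of -4.88.

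The largest increase was in Tnni1 (Entrez 21952), the slow skeletal troponin I that the heart uses before birth. It stood at 0.16 and 0.01 in wild type, where 0.01 is the smallest step of the values and can stand for 0, and at 656 and 994 in the knockout. Its log2 fold change was 9.54 ± 0.23 (SE). Igf2, a growth factor, rose from 8.87 and 4.65 to 311 and 399, and Kcne1, a potassium channel subunit, from 1.03 and 1.28 to 100.1 and 95.6. The other members of the 10 largest increases were Dlk1, Ddc, Mest, Nrep, Cited1, Plagl1 and the histone gene Hist1h2ao, with log2 fold changes of 3.93 to 4.58. Igf2, Dlk1, Mest and Plagl1 are imprinted genes. All 10 had limma adjusted p of 1.75e-05 or less.

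The largest decrease was in Esr1 (Entrez 13982), which encodes estrogen receptor alpha. It stood at 3326 and 2726 in the wild-type libraries, rank 16 of the 17485 genes by wild-type mean, and at 0.09 and 0.03 in the knockout libraries (log2 fold change -11.47 ± 0.19, SE; limma adjusted p = 9.22e-09). Serpina3n, an acute-phase protease inhibitor, fell from 136 and 112 to 0.29 and 0.15, and Bdh1, a mitochondrial enzyme of ketone body use, from 87.6 and 96.4 to 0.11 and 0.10. Complement C3 fell from 213 and 190 to 9.99 and 7.03. Xdh, Ifi205, Cxcl14, Gbp6, Myot and Cpxm2 completed the 10, with log2 fold changes between -4.75 and -4.38. Members of multigene families such as Gbp6, Ifi205, Serpina3n and Hist1h2ao have near-identical copies, and how reads were divided among them was not given.

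**Figure D1:**
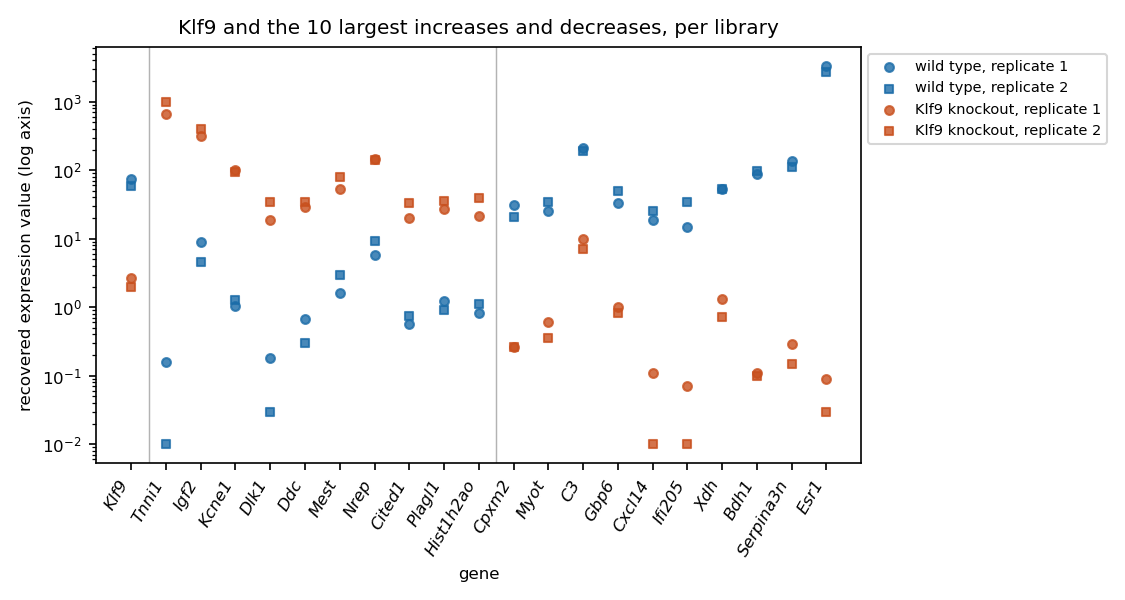
Recovered expression value (log axis) of Klf9, of the 10 largest increases and of the 10 largest decreases in each library, with 1 point per library and vertical lines between the 3 sets. Tnni1 lies at 656 and 994 in the knockout libraries and Esr1 at 3326 and 2726 in the wild-type libraries, and in each gene the libraries of a group lie on the same side of both libraries of the other group.

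Part of the nuclear genes of the respiratory chain and of the mitochondrial ribosome fell in knockout hearts, and with all 4 libraries 0 of them rose. Of 37 complex I genes, 16 fell and 21 did not pass; of 40 genes of complexes II to V, 8 fell and 32 did not pass; of 76 genes of the mitochondrial ribosome, 38 fell and 38 did not pass. Among all 12135 tested genes 2061 were lower, a share close to that in complexes II to V. The list medians were -0.77, -0.49 and -0.66 relative to all tested genes. Examples that fell were Ndufs7 (432 and 503 in wild type, 196 and 212 in the knockout), Ndufb3 (log2 fold change -1.05 ± 0.25), Cox7a1 (895 and 1858 against 270 and 278), Cox8b (-1.13 ± 0.28), Mrpl55 (-1.16 ± 0.20) and Mrpl44 (-0.98 ± 0.18). Cox7a1 and Cox8b encode the muscle isoforms of their subunits. Ndufv1, Atp5g2, Atp5g3, Mrps10 and Mrps11 had log2 fold changes of 0.04, 0.47, 0.36, 0.29 and 0.27 and did not pass, and that of Ndufv1 was negative after RLE (-0.10) or upper quartile (-0.01) scaling. The numbers of lower genes adjusted over the list alone were 18, 5 and 44. The lists passed camera with a preset correlation of 0.01 (adjusted p = 3.35e-07, 0.000196 and 6.90e-10) and not with one estimated from the residuals (adjusted p = 0.523, 0.621 and 0.523 with an estimated correlation) or with fry (adjusted p = 0.185, 0.317 and 0.160). These lists also differed between the wild-type libraries, with medians 0.56, 0.59 and 0.42 higher on the log2 scale in replicate 2 than in replicate 1. Without knockout replicate 1 the counts of lower genes were 1, 1 and 10, and without knockout replicate 2 they were 2, 1 and 8. They were 33, 30 and 66 without wild-type replicate 1 and 16, 5 and 39 without wild-type replicate 2. RLE scaling gave 25, 12 and 52. Complexes II to V had 1 higher gene without either wild-type library in turn. The mitochondrial ribosome had 3 without wild-type replicate 2, where the list medians were -0.48, -0.28 and -0.53. The messenger RNAs of the mitochondrial genome are not analysed here.

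**Figure D2:**
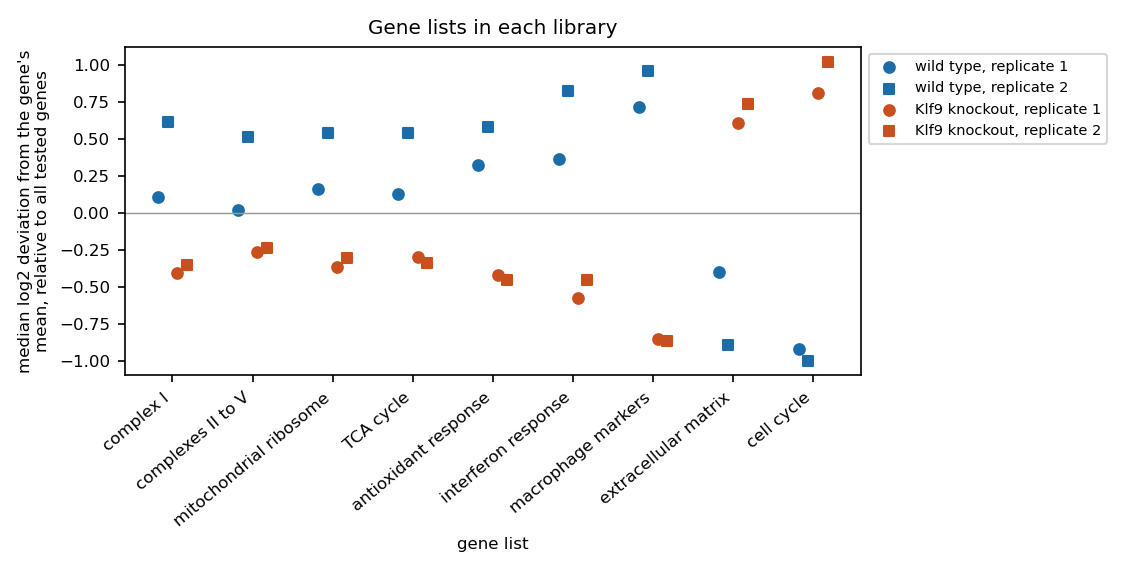
Median over the genes of 9 lists of the log2 deviation from each gene's mean over the 4 libraries, minus that of all tested genes (y axis), in each library (points). In complex I the knockout libraries lie at -0.41 and -0.36 and the wild-type libraries at 0.11 and 0.62, and in the cell cycle list the knockout libraries lie at 0.81 and 1.02.

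The lists of mitochondrial dynamics, mitophagy and mitochondrial gene regulation were called lower by camera with the preset correlation of 0.01 (adjusted p = 0.000393, 0.00218 and 0.0186) and not with an estimated one (adjusted p = 0.503 with an estimated correlation for each). Each had members in both directions. In the dynamics list 13 of 23 genes fell, among them Mtfp1 (84.2 and 91.1 against 33.0 and 33.9), a fission protein of the inner membrane, and Oma1 (-0.99 ± 0.17), while Mtfr2 rose from 0.25 and 0.34 to 1.11 and 1.84. Mief1 (0.38) and the fusion protein Mfn2 (277 and 191 against 241 and 227; log2 fold change 0.02 ± 0.24, limma adjusted p = 0.945) did not pass. In the mitophagy and autophagy list 8 of 28 genes fell and 2 rose: the mitophagy receptor Bnip3 went from 156 and 196 to 24.9 and 23.1, Gabarapl1 changed by -1.92 ± 0.20, and Fkbp8 (0.82) and Tfeb (0.79) rose. Among 24 regulators of mitochondrial biogenesis, 7 fell, including Esrrb (-1.57 ± 0.18), Tfb2m (-1.78 ± 0.21) and Tfam (-0.63 ± 0.21), and 3 rose, including Ppargc1b (1.37 ± 0.22) and Nrf1 (0.71 ± 0.17). Ppargc1a, the best-known coactivator of this group, did not pass (34.8 and 29.8 against 35.0 and 30.01; log2 fold change 0.01 ± 0.19, limma adjusted p = 0.975). The fold changes of Mfn2 and Ppargc1a were negative after RLE scaling (-0.12 and -0.13). The list medians were -0.67, -0.40 and -0.45 relative to all tested genes. When adjusted over the list alone, 14, 7 and 8 genes were lower and 1, 2 and 3 higher. Lower genes numbered 6, 4 and 4 without knockout replicate 1, where the biogenesis list no longer passed (adjusted p = 0.0518), 2, 4 and 3 without knockout replicate 2, and 16, 14 and 11 without wild-type replicate 1. Higher genes numbered 1, 1 and 2 without knockout replicate 1 and 1, 0 and 1 without knockout replicate 2. Without wild-type replicates 1 and 2 they numbered 2, 3 and 4 and 2, 2 and 4.

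Of the lists of fuel use, those of the tricarboxylic acid cycle and of glycolysis were called lower by camera with the preset correlation (adjusted p = 0.000184 and 0.00122) and not with an estimated one (adjusted p = 0.523 and 0.503 with an estimated correlation). In fatty acid oxidation members went both ways. In the list of the tricarboxylic acid cycle 10 of 22 genes fell (Pdhx -1.38 ± 0.21, Suclg2 -0.92 ± 0.19) and 12 did not pass, with Idh2 at 0.27. In the glycolysis and glucose uptake list 8 of 22 fell, with Slc2a4, the insulin-responsive glucose transporter, going from 225 and 200.3 to 70.4 and 59.96 and Pfkfb1 changing by -2.27 ± 0.19, and Eno1 rose (0.86 ± 0.23) while Hk1 did not pass (0.41). In the fatty acid oxidation list 5 of 30 genes rose and 8 fell: Acot1 went from 6.11 and 7.15 to 43.5 and 63.3, while Cd36, a fatty acid transporter, went from 527 and 892 to 246 and 232 and Etfa changed by -1.09 ± 0.25. That list did not pass (camera adjusted p = 0.320), and its median was -0.29 relative to all tested genes while its mean log2 fold change was 0.07. In the antioxidant list 20 of 30 genes fell, led by the glutathione transferases Gstm1 (163 and 163 against 21.9 and 22.6) and Gstm2 (-2.75 ± 0.19), which are close paralogs; Ucp2, an uncoupling protein, rose from 80 and 77.5 to 337 and 270, and Prdx2 did not pass (0.34). The antioxidant list had a median of -0.86 and a camera adjusted p of 3.35e-07, with adjusted p = 0.503 with an estimated correlation. Adjusted over the list alone, lower genes in the cycle, glycolysis, oxidation and antioxidant lists numbered 10, 8, 8 and 20 and higher genes in the last 3 numbered 1, 6 and 1. Without knockout replicate 1 the lower counts of these 4 lists were 2, 5, 1 and 11, and without knockout replicate 2 they were 2, 4, 1 and 12. Without wild-type replicate 1 they were 17, 10, 13 and 22. Higher genes in the last 3 lists numbered 0, 4 and 1 without either knockout library in turn. They numbered 2, 8 and 1 without wild-type replicate 1 and 1, 7 and 4 without wild-type replicate 2. The median of the oxidation list was -0.45 without wild-type replicate 1 and -0.125 without wild-type replicate 2.

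Cell cycle genes had the highest median of the 34 lists tested. Whether the changes in this paragraph come from the loss of Klf9 or from a younger stage of the knockout hearts was not tested. In the knockout 23 of 26 genes rose, with a median of 1.83 relative to all tested genes; Rrm2, which supplies deoxynucleotides, went from 1.60 and 1.86 to 25.4 and 26.9, and the proliferation marker Mki67 from 1.03 and 1.16 to 17.0 and 20.8. Cdkn1a, a cell cycle inhibitor, did not pass (114 and 43.7 against 37.8 and 53.5). Extracellular matrix genes rose in 20 of 30 cases and fell in 4: elastin (Eln) went from 19.3 and 12.2 to 202 and 198 and periostin (Postn) from 18.4 and 23.0 to 138 and 138, while Mmp3 went from 5.66 and 8.64 to 0.07 and 0.01 and Col8a1 changed by -1.86 ± 0.18. Among immediate early genes 13 of 19 rose, including Fos (1.19 and 0.81 against 8.82 and 8.48) and Nr4a1 (11.96 and 7.30 against 77.1 and 120.4), Cyr61 fell (-0.98 ± 0.23) and Ier3 did not pass (-0.46). All 6 tested epicardial markers rose, for example Wt1 (4.82 and 3.69 against 7.55 and 9.82) and Upk3b (2.21 ± 0.35). Camera gave adjusted p of 6.90e-10 for the cell cycle, 0.00122 for matrix, 0.00175 for immediate early and 0.00324 for epicardial genes, and adjusted p = 0.503, 0.516, 0.516 and 0.503 with an estimated correlation. In these 4 lists 23, 20, 13 and 6 genes were higher when adjusted over the list alone. Among immediate early genes 0 fell without knockout replicate 1 and 2 without either wild-type library in turn, and 1 cell cycle gene fell without wild-type replicate 2. Of the cell death list, 9 of 23 genes rose, among them Bcl2l11 (1.66 ± 0.21), and 4 fell, among them Diablo (-0.99 ± 0.22) and Bcl2l1 (-0.79 ± 0.19); it did not pass (camera adjusted p = 0.323). Without knockout replicate 2, 4 genes of that list rose and 1 fell, and without knockout replicate 1, 8 rose and 0 fell.

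Most tested genes of the interferon, inflammation and macrophage lists fell in knockout hearts. In the interferon list 16 of 23 genes fell and 7 did not pass, with a median of -1.15; Oas2, an antiviral synthetase, went from 14.7 and 12.5 to 0.58 and 0.70, Oas1a changed by -1.62 ± 0.16, and Gbp3 did not pass (3.01 and 6.0 against 5.22 and 3.90), with a negative fold change after RLE scaling (-0.06). In the inflammation list 11 of 17 genes fell, including Lcn2 (26.3 and 25.3 against 0.40 and 0.85) and S100a9 (10.4 and 12.02 against 0.68 and 1.31), and Sele (1.17 ± 0.18) and Vcam1 (0.71 ± 0.17), adhesion molecules of the endothelium, rose. Of 10 macrophage markers 8 fell and 1 rose, with C1qa at 55.5 and 74.0 against 16.3 and 15.7 and Lyz2 at 71.9 and 169 against 14.8 and 15.5. Of 5 tested neutrophil markers 3 fell and 1 rose, S100a8 by -1.97 ± 0.16; S100a9 is in this list as well. The camera adjusted p was 3.73e-08 for interferon, 0.000274 for inflammation, 0.000111 for macrophage and 0.0329 for neutrophil genes, and adjusted p = 0.503 with an estimated correlation for each. Lower genes numbered 17, 11, 9 and 3 when adjusted over the list alone. The neutrophil list did not pass after RLE scaling (adjusted p = 0.0569) or without wild-type replicate 1 (adjusted p = 0.132). Higher genes in the inflammation list numbered 4 without wild-type replicate 1 and 1 without either knockout library in turn. In the neutrophil list 0 genes were higher without either knockout library or after RLE scaling. The interferon list had 1 higher gene without wild-type replicate 2.

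Among genes known to respond to glucocorticoids, a list that includes Klf9, 12 of 18 fell and 3 rose, with a median of -1.07 (camera adjusted p = 6.65e-06; adjusted p = 0.503 with an estimated correlation). Lcn2 was among those that fell, and Angptl4 (13.0 and 15.1 against 29.6 and 47.1) and Dusp1 (0.77 ± 0.18) rose. Of 15 other Krüppel-like factors 6 rose, including Klf11 (4.56 and 4.17 against 17.3 and 17.3) and Klf2 (1.05 ± 0.19), Klf15 fell from 22.4 and 27.6 to 4.47 and 3.42, and Klf12 did not pass (-0.04); the list did not pass (camera adjusted p = 0.125). Heat shock and chaperone genes fell in 11 of 19 cases, for example Hsph1 (47.2 and 52.2 against 5.43 and 6.59) and Hspb8 (353 and 355 against 74.8 and 72.3), and Dnajb1 rose (0.55 ± 0.18; camera adjusted p = 2.73e-06 for the list and adjusted p = 0.503 with an estimated correlation). In the list of the integrated stress response 7 of 24 genes rose, among them the serine synthesis enzymes Phgdh (1.31 ± 0.19) and Psat1 (1.45 ± 0.21), and 10 fell, among them Cebpb (-1.94 ± 0.20) and Chac1 (-1.29 ± 0.30); the list did not pass (camera adjusted p = 0.135). Clock genes did not pass as a list (camera adjusted p = 0.969; median -0.04 relative to all tested genes, mean log2 fold change 0.15), with 6 of 19 higher, including Hlf (1.16 ± 0.18) and Npas2 (1.48 ± 0.23), and 2 lower, Nr1d1 (-0.95 ± 0.19) and Bhlhe41 (-0.55 ± 0.20). Of 23 ubiquitin and proteasome genes 3 fell, including the muscle ring finger gene Trim54 (158 and 129 against 13.8 and 9.12) and the ubiquitin ligase Fbxo32 (-1.28 ± 0.23), Trim55 rose (1.69 ± 0.21) and Foxo1 did not pass (0.32); the list's camera adjusted p was 0.0373, with adjusted p = 0.503 with an estimated correlation, and it did not pass without wild-type replicate 2 (adjusted p = 0.104), without knockout replicate 1 (0.0692), without knockout replicate 2 (0.0646) or with a filter of at least 5 in 2 libraries (0.0664). Adjusted over the list alone, the glucocorticoid, Krüppel-like, heat shock, stress, clock and ubiquitin lists had 3, 7, 1, 7, 5 and 1 higher and 12, 1, 12, 10, 1 and 3 lower genes. Without knockout replicate 1 the stress list had 5 lower, the clock list 3 higher and the glucocorticoid list 1 higher genes. Without knockout replicate 2 the stress list had 4 higher and 6 lower, the Krüppel-like list 3 higher and the clock list 1 lower genes. Without wild-type replicate 1 the Krüppel-like list had 10 higher, the clock list 6 lower and the ubiquitin list 2 higher and 7 lower genes. In the heat shock list 0 genes were higher without either knockout library in turn or after RLE scaling, and 2 without wild-type replicate 2. The clock median was -0.11 without wild-type replicate 1, 0.14 without wild-type replicate 2, -0.21 without knockout replicate 1 and 0.11 without knockout replicate 2.

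Contractile genes showed changes in both directions. In the hypertrophy and fetal gene list 9 of 17 rose and 6 fell: Acta2 went from 89.7 and 74.6 to 255 and 358 and the atrial light chain Myl4 from 1.79 and 2.0 to 5.61 and 7.75, while skeletal actin Acta1 went from 814 and 313 to 45.2 and 70.9 and Xirp2 changed by -2.61 ± 0.20. In the sarcomere and Z-disc list 4 of 20 fell, including Tcap (364 and 635 against 127 and 112) and Myoz2 (-0.86 ± 0.25), Myom2 rose from 154 and 126 to 382 and 332, and Mybpc3 did not pass (0.48). Neither list passed (camera adjusted p = 0.901 and 0.136). Of 28 calcium handling and ion channel genes 6 fell and 3 rose: the sodium channel subunit Scn4b went from 17.4 and 15.3 to 0.17 and 0.05, Kcnj3 from 18.3 and 22.8 to 3.83 and 3.09, and Kcnh2 (0.90 ± 0.19) and Fkbp1b (0.59 ± 0.16) rose. This list's camera adjusted p was 0.0322, with adjusted p = 0.516 with an estimated correlation, and it did not pass without wild-type replicate 1 (adjusted p = 0.178) or with a filter of at least 5 in 2 libraries (0.0802). In the cytosolic ribosome list 66 of 71 genes did not pass, Rps27 (-0.44) among them; Rpl3 (1.33 ± 0.22) and Rpl36 (0.88 ± 0.21) were among the 4 that rose, and Rpl34 fell (-1.62 ± 0.28; camera adjusted p = 0.320 for the list). Ribosomal protein genes have many processed copies. Without wild-type replicate 2, 42 of these genes rose and the list passed (adjusted p = 0.000248), and without wild-type replicate 1, 7 rose and 12 fell. Without either knockout library in turn 1 rose. Adjusted over the list alone, the fetal, sarcomere, channel and ribosome lists had 9, 1, 2 and 1 higher and 6, 2, 6 and 1 lower genes. Without knockout replicate 1 the fetal, sarcomere and channel lists had 8, 1 and 1 higher and 2, 1 and 5 lower genes. Without knockout replicate 2 they had 6, 1 and 0 higher and 3, 1 and 4 lower genes. Without wild-type replicate 1 these counts were 7, 5 and 8 higher and 6, 8 and 9 lower, and without wild-type replicate 2 they were 7, 3 and 5 higher and 7, 6 and 12 lower.

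Markers of other cell types of a whole heart were examined as lists fixed beforehand. Among fibroblast markers 5 of 12 rose and 3 fell (Gsn 419 and 340.0 against 69.2 and 72.2, Dcn -1.16 ± 0.30; camera adjusted p = 0.320), and without knockout replicate 2 the list passed in the upward direction (adjusted p = 0.0428). Among smooth muscle and pericyte markers 7 of 12 rose and 1 fell, with Rgs5 at -1.03 ± 0.26 (camera adjusted p = 0.0757), and among endothelial markers 4 of 12 rose, Cdh5 by 0.85 ± 0.20, and 1 fell, while Eng did not pass (-0.48; camera adjusted p = 0.784). The smooth muscle list had 4 higher and 0 lower genes without knockout replicate 2 and 4 higher after RLE scaling. The endothelial list had 1 higher and 0 lower without either knockout library in turn, and 2 and 3 lower without wild-type replicates 1 and 2. Of 6 atrial markers 3 rose and 2 fell, Kcnj3 and Nppa (232 and 195 against 93.8 and 134; camera adjusted p = 0.901). Red cell genes did not pass as a list (camera adjusted p = 0.526), with Hba-a1 at 4125 and 3721 against 7268 and 5051 and its near-identical copy Hba-a2 at 3335 and 2723 against 6210 and 4003; of 9 genes 1 rose and 1 fell. Without wild-type replicate 1, 3 red cell genes rose, and without either knockout library in turn 0 fell. In the atrial list 1 gene fell without knockout replicate 1. Adjusted over the list alone, higher genes in the fibroblast, smooth muscle, endothelial, atrial and red cell lists numbered 5, 7, 4, 3 and 1 and lower genes 3, 1, 1, 2 and 0. Lists with fewer than 5 tested genes had no list test. Of 4 adipocyte markers 2 fell, while Fabp4 (749 and 1704 against 690 and 800; log2 fold change -0.60, limma adjusted p = 0.204) and Cidea (0.36) did not pass. Without either wild-type library in turn 1 adipocyte marker rose. Of 4 skeletal muscle markers 2 fell, Acta1 among them, and 1 rose, while Ckm did not pass (1566 and 1457 against 1608 and 1556) and was negative after RLE scaling (-0.08). Of 3 Schwann cell and neuronal markers 2 rose and Pmp22 did not pass (-0.19). Of these, 0 rose without knockout replicate 1 and 1 without knockout replicate 2 or wild-type replicate 2. The single tested lung marker Ager rose from 0.24 and 0.16 to 3.07 and 2.64. Lymphocyte and thymus markers had 0 genes that reached the filter.

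**Figure D3:**
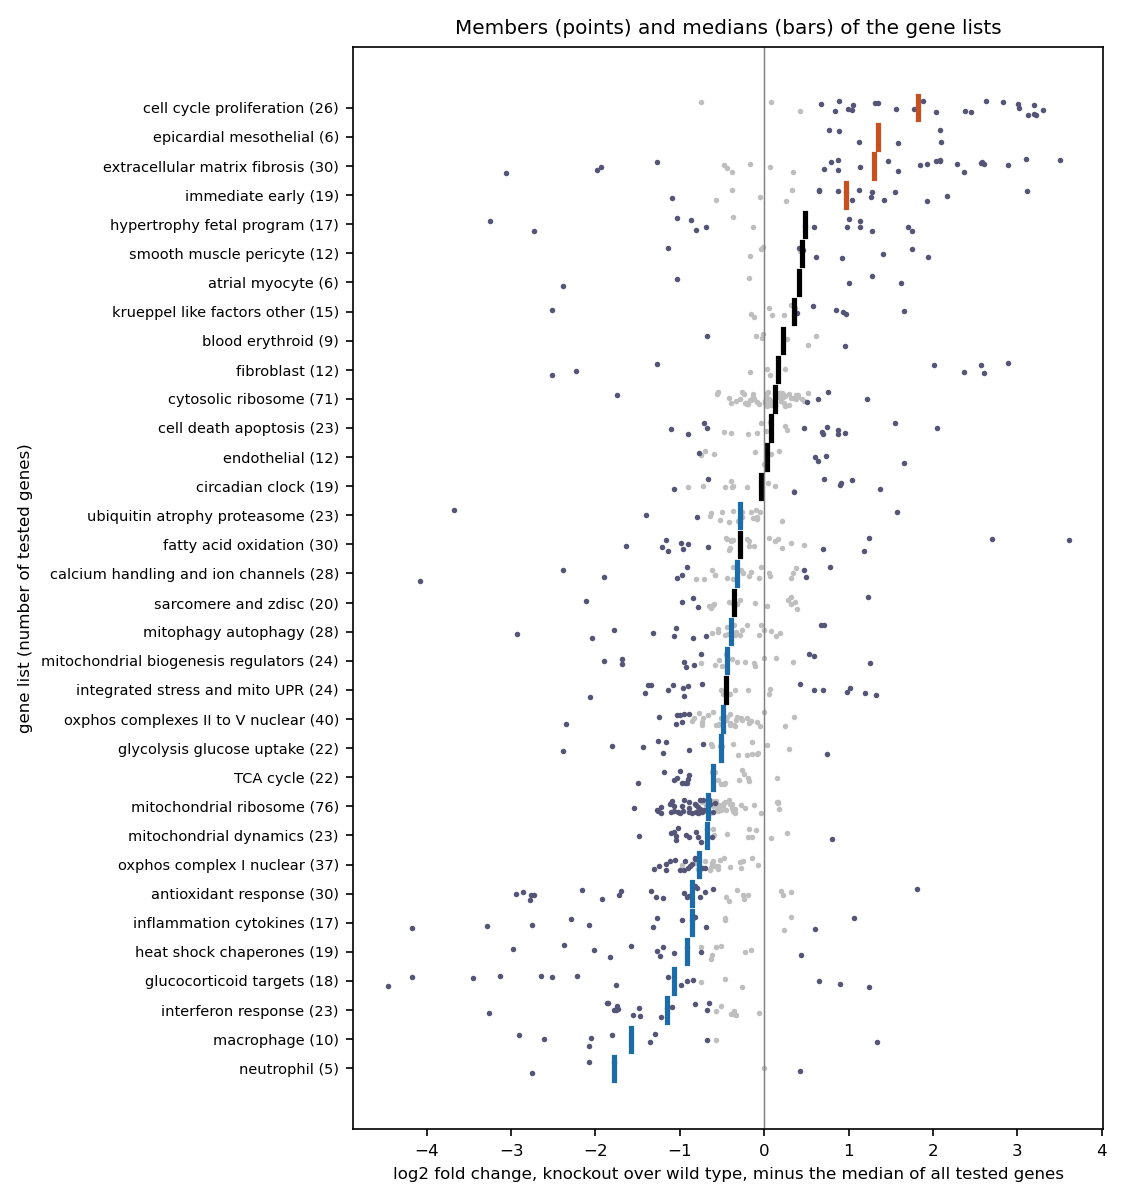
Log2 fold change of knockout over wild type minus the median of all tested genes (x axis) for the members of the 34 lists with at least 5 tested genes (points, dark where the limma adjusted p is below 0.05) and the list medians (bars, orange or blue where camera with the preset correlation of 0.01 called the list higher or lower, black otherwise). Cell cycle genes have the highest median at 1.83 and neutrophil markers the lowest at -1.79.

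Of the 34 lists with enough genes, 4 were called higher and 17 lower by camera with the preset correlation. With the correlation estimated from the residuals of 4 libraries 0 lists passed, 0 had an unadjusted p below 0.05 and the smallest unadjusted p was 0.0518. These failures cannot be laid to correlation between genes alone. The estimate was -0.00012 for mitophagy and -0.052 for inflammation, yet their camera adjusted p also went to 0.503. For complex I, complexes II to V and the mitochondrial ribosome it was 0.80, 0.73 and 0.70. Fry, which asks whether the genes of a list move 1 way on balance, called 7 lists. Those were, in the upward direction, cell cycle (adjusted p = 0.0386) and fibroblast genes (0.0368), the latter not called by camera. In the downward direction they were mitophagy (0.0368), glucocorticoid (0.0386), inflammation (0.00931), heat shock (0.0495) and neutrophil genes (0.00327).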

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

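Alternatives that change the filter to at least 5, drop the variance trend, leave out the X and Y chromosomes or recount lists without a library were chosen after seeing the data. The direction of the Klf9 decrease and its call held under all settings run, and 0 of the 5428 genes called with limma at an adjusted p below 0.05 had the opposite sign in any of them where tested. Counts of higher and lower genes stayed within 1.5 times of 3367 and 2061 under other scalings, filters, pseudocounts, thresholds and variance settings. Leaving out a library in turn gave 1859 to 4327 higher and 1100 to 3261 lower genes, with the lowest counts without knockout replicate 2 and the highest without wild-type replicate 1; the remaining library of that group was assumed to vary like the other group, whose spread differed (SD of the log2 difference between replicates 0.393 in wild type and 0.218 in the knockout), and fewer libraries were tested.

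With an estimated correlation 0 lists were called higher and 0 lower, and with fry 2 were called higher and 5 lower, against 4 and 17 in the main test. Genes whose sign turned had not passed in the main test. After RLE scaling Ndufv1 stood at -0.10, Gbp3 at -0.060, Ckm at -0.082, Mfn2 at -0.12 and Ppargc1a at -0.13, and after upper quartile scaling Ndufv1 stood at -0.013, Mfn2 at -0.033 and Ppargc1a at -0.046; RLE scaling lowers knockout values relative to wild type. With each library left out in turn, log2 fold changes ranged from -0.043 to 0.13 for Ndufv1, -0.091 to 0.0014 for Klf12, -0.34 to 0.46 for Gbp3, -1.32 to 0.042 for Cdkn1a, -0.24 to 0.29 for Mfn2 and -0.10 to 0.12 for Ppargc1a; beyond the choice of libraries the cause was not tested. The list of Krüppel-like factors passed with no filter (adjusted p = 0.0452). With the filter of at least 5 the channel (adjusted p = 0.0802) and ubiquitin (0.0664) lists did not pass. Lists whose direction turned had not passed in the main test either. Writing the camera p as negative where a list lay lower, fetal genes stood at -0.991 with no filter and -0.818 with the filter of at least 5, atrial markers at -0.770 with that filter, and clock genes at -0.985 with a pseudocount of 0.1. For fatty acid oxidation fry, which does not compare a list with other genes, gave a p of 0.653 in the upward direction. With each library left out the signed camera p ranged from -0.690 to 0.679 for fetal genes, -0.982 to 0.715 for atrial, -0.887 to 0.518 for red cell, -0.837 to 0.806 for endothelial, -0.747 to 0.817 for clock and -0.792 to 0.127 for cytosolic ribosome genes.

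The replicate number as a block gave 3514 higher and 2275 lower genes, with 22, 14 and 44 lower genes in complex I, complexes II to V and the mitochondrial ribosome. The labels do not say that a number pairs libraries, and the deviations of same-numbered libraries correlated at -0.0355 over 2 pairs, so the numbers were not taken as pairs. Under the block the lists of biogenesis regulators (adjusted p = 0.0517) and ubiquitin genes (0.0659) did not pass. Not run were DESeq2, limma-voom, the quasi-likelihood test without robust settings and a minimum of 50 counts, which need counts, the scaling without genes of the mitochondrial genome, since the table used here has 0 genes with a symbol starting mt-, and a second unit. Depth is unknown, so it cannot be said for which low genes counting limits the precision.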

Other observations

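The lists and tests in this part were written after the first results were seen, except the test of transcript length and GC content, which was written before its result. Of the genes of complement and antigen presentation, leaving out 5 that had been named or stood in a fixed list, 14 of 15 fell, with a median of -2.12 relative to all tested genes (camera adjusted p = 4.34e-11 over 3 such lists; adjusted p = 0.244 with an estimated correlation). The invariant chain Cd74 went from 39.3 and 47.2 to 5.89 and 5.47 and B2m from 263 and 553 to 99.4 and 102.4, while Tap1 did not pass (-0.35). C4b, a complement component outside that count, went from 19.1 and 15.8 to 0.15 and 0.16. C3, C4b and the macrophage genes C1qa, C1qb and C1qc were those left out. Of the 10 tested macrophage markers, which include these C1q genes, 8 fell as well, with a list median of -1.57. Whether fewer macrophages account for the fall was not tested. Of imprinted and growth genes that decline after birth, a list prompted by Igf2, Dlk1, Mest and Plagl1 among the largest increases, 11 of 12 rose when these 4 and Cdkn1c were left out (median 1.53; camera adjusted p = 7.76e-07, and adjusted p = 0.128 with an estimated correlation), among them Peg3 (2.30 and 1.58 against 22.7 and 21.8), Gpc3 (0.84 and 1.53 against 17.7 and 17.9) and the RNA-binding protein Igf2bp3 (0.50 and 0.34 against 4.93 and 7.76).

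Genes of ketone body use and lipid handling changed in both directions. Oxct1, which acts with Bdh1 in ketone body use, went from 334 and 486 to 56.2 and 56.1, lipoprotein lipase Lpl from 1563 and 1596 to 302 and 272, and Thrsp from 19.8 and 30.2 to 2.04 and 1.49, while the desaturases Scd4 (4.81 and 4.46 against 72.5 and 73.4) and Scd2 (4.97 and 5.84 against 34.3 and 31.7) and fatty acid synthase Fasn (4.48 and 3.11 against 15.6 and 17.5) rose. Of 12 tested genes of this list that had not been named and stood in no fixed list 4 rose and 4 fell (camera adjusted p = 0.309).

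The knockout libraries differed in Y-linked genes, although both are labelled male. In replicate 1 Ddx3y, Eif2s3y, Kdm5d and Uty stood at 7.82, 27.0, 4.01 and 3.57, and in replicate 2 at 0.01, 0.73, 0.01 and 0.58, against 14.6, 23.6, 3.42 and 4.68 in wild-type replicate 1 and 17.1, 41.8, 3.97 and 7.31 in wild-type replicate 2. Their 4 partners on the X chromosome were higher in replicate 2 than in replicate 1, by a median of 0.40 on the log2 scale. Between the knockout libraries 5 other tested genes differed by at least 1.53 on that scale, the smallest difference of a Y-linked gene (Uty). These 5 did not reach the differences of Kdm5d, Ddx3y and Eif2s3y (-2.31, -3.13 and -4.02, replicate 2 over replicate 1). The male label of knockout replicate 2 is thus in doubt. Sex was left out of the fit because all 4 labels say male. Leaving out genes of the X and Y chromosomes does not remove effects of sex on other genes. Knockout replicate 1, which had Y-linked transcripts, still differed broadly from wild type. Its Spearman's rho across genes was 0.885 and 0.849 with the wild-type libraries and 0.991 with knockout replicate 2. How much sex adds to the change of single genes was not tested. Nnt, part of which is deleted in a C57BL/6 substrain, stood at 166 and 135 in wild type and 106 and 98.5 in the knockout (limma adjusted p = 0.0619). Sequence outside the deleted part can leave a remainder, so these values do not tell which allele the animals carried.

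Tnni1 had the largest increase in the knockout libraries. The hypertrophy and fetal gene list fixed beforehand did not pass (9 of 17 genes higher, 6 lower; camera adjusted p = 0.901). Skeletal muscle in the knockout samples was considered as the source of Tnni1. Beside 656 and 994 for Tnni1, 16 other skeletal muscle transcripts, most of them of fast fibres, had a median of 0.44 there. Apart from Mb (4224 and 3828), which the heart expresses and which fell, the highest value was 70.9. The low median argues only against fast-fibre muscle, to which Tnni1, a slow muscle gene, does not point. Slow muscle would leave that median low as well, so the median cannot exclude it. Tnnt1, the slow troponin T, rose but only to 42.0 and 31.5, Casq1 rose to 13.6 and 12.7, and Acta1 fell. In 14 textbook isoform pairs that switch after birth the ratio of immature to mature isoform shifted by a median of 1.211 on the log2 scale (range -0.10 to 2.19) and was higher in both knockout libraries in 13, against 38.2% of 10000 random pairs of tested genes, but this tests nothing anew, since 8 pairs hold a gene already named and 1 pair has no member in the fixed lists. A younger stage of the knockout hearts, against the stated age of 8 weeks, and a maturation delayed by the loss of Klf9 may each give such a shift and cannot be told apart, because the pairs are void as a test, the labels give 1 age and 0 wild-type libraries reached the pair ratios of the knockout libraries.

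Esr1 was among the most abundant transcripts of both wild-type libraries and near the smallest step in both knockout libraries. A candidate explanation is a transgene that carries part of Esr1 in the wild-type animals, such as an inducible Cre recombinase fused to its ligand-binding domain. The level was 0.468 and 0.569 of that of Myh6. Of 6 tested neighbours on the chromosome 1 was higher in wild type, Rmnd1 (46.5 and 61.9 against 34.1 and 36.9), and 2 were lower, Akap12 and Mthfd1l. As a set the 6 neighbours were not raised with Esr1, with a median log2 ratio of wild type over knockout of -0.159. The test by neighbours could have excluded a transgene, but an endogenous gene raised alone would give the same value. No reads were analysed here to tell which exons were present. Whether the receptor was active cannot be told apart from an inert transcript, because 6 tested targets had a median log2 ratio of -0.275 with 1 higher and 2 lower in wild type. The targets C3 and Lcn2, both higher in wild type, were left out as already seen. A further 4 targets were too low to be tested. In wild type Greb1 stood at 0.27 and 0.17, Ltf at 0.67 and 0.25, Pgr at 0.02 and 0.01 and Myb at 0.01 in both libraries. The loss of Klf9 as the cause of the difference in Esr1 between the groups stays open and untested. If the wild-type animals carried such a transgene, the groups would differ in more than Klf9. That difference would then enter every comparison made here, and this too was not tested.

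The respiratory chain and mitochondrial ribosome lists (153 genes, most of which did not pass) also differed between the wild-type libraries, by a median of 0.465 on the log2 scale relative to all genes. A correction of each library for transcript length and GC content moved fold changes by a median of 0.135 and the median of these genes from -0.658 to -0.648 (SE over genes 0.037), which argues against these properties as the whole cause. Wild-type replicate 2 as the sole cause is argued against by a median of -0.475 (SE over genes 0.035) without it, beside -0.882 without wild-type replicate 1; these SEs treat genes as independent, which they are not. The size of the shift thus depends on which wild-type library is used. A younger or less mature heart, in which these genes are lower, the loss of Klf9, and an unlabelled difference between the groups stay open as untested.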
